A study of Drosophila melanogaster with 12 samples.

How the data were processed

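RNA was measured in oocytes and eggs of Drosophila melanogaster in 12 libraries, 2 for each of 6 groups made of 2 genotypes and 3 stages. Per the labels' protocols, immature and mature oocytes were dissected by hand in Grace's medium from females aged 3 to 4 days. Activated unfertilized eggs came from virgin females mated to sterile males, the sons of tud1 mothers, and eggs were collected at 25 °C. Per the labels' protocols, total RNA was extracted with TRIzol, an equal amount of ERCC spike-in RNA was added, ribosomal RNA was removed with Ribo-Zero, and libraries were made with the TruSeq RNA kit v2. The stage, genotype and replicate number of each library were taken from the labels.

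The deposited table holds the authors' normalised read counts, a signal that is never negative and is not whole numbers, for each transcript record. The submitters' processing notes name STAR 2.4.2a, HTSeq (version not given), RSEM 1.2.25 and the genome build dm6, without their roles. The method of normalisation is not given in the sources used here. Of 5422 records 1 was an identical duplicate and was removed, which left 5421. The lowest value in any library was 100.07, so a gene is in the table only if it reached 100 in each of the 12 libraries. Genes that fell below that level in some group are missing, and falls near it are understated. The table used here has 0 ERCC rows, so values could not be scaled to the spike-ins here. Whether the deposited values were already scaled to them is not given in the sources used here, so it is open whether a shift shared by all transcripts of a stage or genotype would show in these values, and how a median of all genes away from 0 is to be read. No step that turned the values into whole reads was found. The best step made 18.7% of the low values whole within a tolerance of 0.05, where chance gives 10%. Sequencing depth is therefore unknown, and no counting interval is given. The library sums ranged from 11081267 to 14089899, and records with noncoding accessions made up 10.4% to 25.8% of them.

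Record accessions were matched to RefSeq genes (5391 matched) and to gene models with transcript lengths and coordinates (5399 matched), and 5347 were protein coding. Values were analysed as log2(value + 1), so fold changes are on that scale. A filter on a mean of at least 10 removed 0 genes. A single limma fit (limma 3.58.1, R 4.3.3, with an intensity trend) estimated the 6 group means, with 6 residual degrees of freedom and 2.43 prior degrees of freedom, and 9 contrasts were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The replicates are biological per the labels, but with 2 per group the spread rests mainly on pooling over groups, and a group with a larger spread than the others is given too small an error. The fit had no block, as set beforehand. The series text speaks of 2 sets without tying them to the replicate numbers. Across genes the deviations of same-numbered libraries from their group means correlated between genotypes at 0.849 in immature, 0.483 in mature and 0.771 in activated libraries, at 0.217 to 0.618 between mature and activated groups, and at -0.938 to -0.31 between immature and other groups, so a number went with a shared deviation within a stage and not over all stages.

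The contrasts, tests, gene lists and the rule for named genes were set before the data were examined. For the comparisons between genotypes at each stage and the 2 wild type transitions, the rule took wisp, the 8 largest increases and 8 largest decreases among called genes whose groups did not overlap and whose higher mean was at least 100, without genes known only by an annotation number, and from each list up to 4 called members or, with none called, the 2 most abundant. For the other contrasts it took 5 in each direction. Of 31 lists, 20 had at least 3 members in the table. They cover follicle cell, nurse cell and germline markers, cytoplasmic and mitochondrial ribosomal proteins, oxidative phosphorylation, proteasome, CCT chaperonin, glycolysis, vacuolar ATPase, both kinds of histones, cell cycle, egg activation, axis patterning, Toll pathway, poly(A) tail control, piRNA, heat shock, translation factor and ecdysone genes. Each was tested with camera in limma at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment within each contrast. No camera call held with the estimated correlation.

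The code was tested on simulated data with known changes for mutant against wild type mature oocytes over 5421 genes. Of 50 genes per size, 35 were recovered at a log2 change of -2, 20 at -1, 24 at 1 and 37 at 2, and 1 of 5221 unchanged genes was called. The noise was drawn independently for each gene and library, without the shared deviations of same-numbered libraries. These rates therefore do not carry over to the data or to the other contrasts. Alternatives were other pseudocounts (0.5 and 5), filters, TMM, median-of-ratios and quantile scaling, a fit without a trend, a fold threshold, a replicate block, fits with fewer libraries, and each replicate left out in turn. A length correction, which removed from each library the smooth trend of its deviations on transcript length, a filter at a mean of 500, a block within each stage, a fit without the 4 immature libraries and a fit on protein-coding records were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.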

Results

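The series measured RNA in oocytes and eggs of Drosophila melanogaster by sequencing of total RNA after removal of ribosomal RNA. Wild type flies (w1118) were set against flies with an allele of wispy (wisp) that the labels call null (wispKG5287). The gene encodes a poly(A) polymerase that lengthens the tails of maternal mRNAs in the cytoplasm. For each genotype the labels give 3 stages. These are immature oocytes from oogenesis stages 9 to 10, mature oocytes from stage 14, and activated unfertilized eggs aged 0 to 1 h. The labels call the 2 replicates of each of the 6 groups biological, the series text speaks of 2 sets, and there were 12 libraries. The deposited values are the authors' normalised read counts for 5421 distinct transcript records, called genes here. The sum of the values ranged from 11081267 in replicate 1 of wild type mature oocytes to 14089899 in replicate 2 of mutant activated eggs. The depth of sequencing behind these sums is unknown, and the smallest value in any library was 100.07. A gene that fell below 100 in 1 library is not listed, so losses below that level are not seen here.

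The replicates differed in how close they lay, depending on the stage. Across genes the log2 values of the replicates correlated at 0.993 in wild type mature oocytes and 0.994 in mutant mature oocytes. The correlation was 0.828 and 0.858 in wild type and mutant immature oocytes, and 0.957 and 0.914 in wild type and mutant activated eggs. In wild type immature oocytes 1117 genes differed by at least 2-fold between replicates, against 9 genes in wild type mature oocytes. Wild type immature replicate 1 correlated at 0.973 and 0.967 with the wild type mature replicates, above the 0.828 with immature replicate 2. Mutant immature replicate 1 correlated at 0.918 and 0.912 with the mutant mature replicates, above the 0.858 with immature replicate 2. Genes are not independent replicates, so these correlations carry no p-value.

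**Figure D1:**
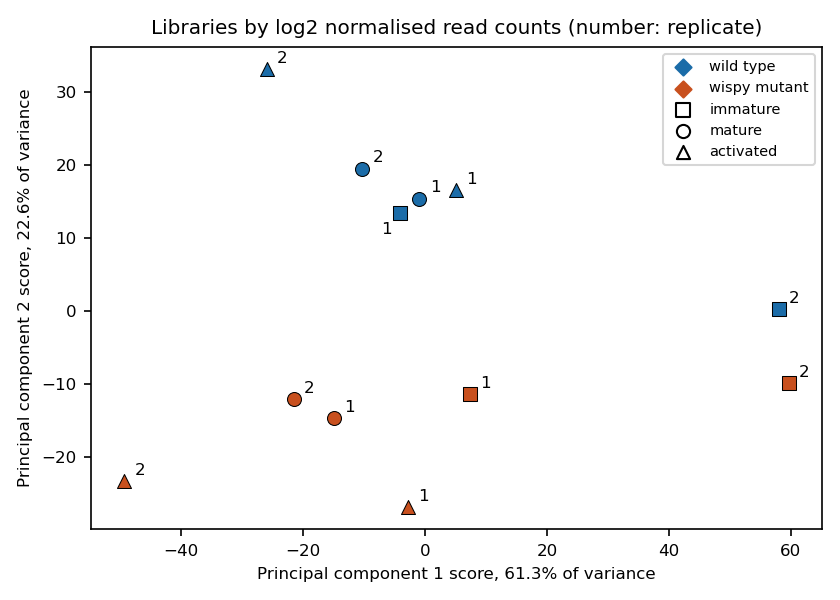
Each point is 1 library, placed by its scores on the first and second principal components of the log2 normalised read counts, with colour for genotype, shape for stage and a digit for the replicate. Replicate 2 of the immature oocytes lies at 58 and 59.7 on the first component (61.3% of the variance), away from replicate 1 at -4.12 and 7.34.

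The wisp gene itself (chromosome X, 11893943 to 11899920, plus strand, dm6) was low in each of the 6 mutant libraries. In immature oocytes its normalised read count was 6909 ± 4650 (SD, n = 2) in wild type and 483.5 ± 332 (SD, n = 2) in the mutant. In mature oocytes it was 8767 ± 1350 (SD, n = 2) against 254 ± 6.87 (SD, n = 2). In activated eggs it was 12260 ± 7020 (SD, n = 2) against 292.8 ± 147 (SD, n = 2). The log2 fold change of wisp was -3.84 in immature oocytes (limma, adjusted p = 0.0676, which missed the threshold, and 5.17e-11 with a block for the replicate number within each stage), -5.10 in mature oocytes (limma, adjusted p = 0.00294) and -5.35 in activated eggs (limma, adjusted p = 0.00222).

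**Figure D2:**
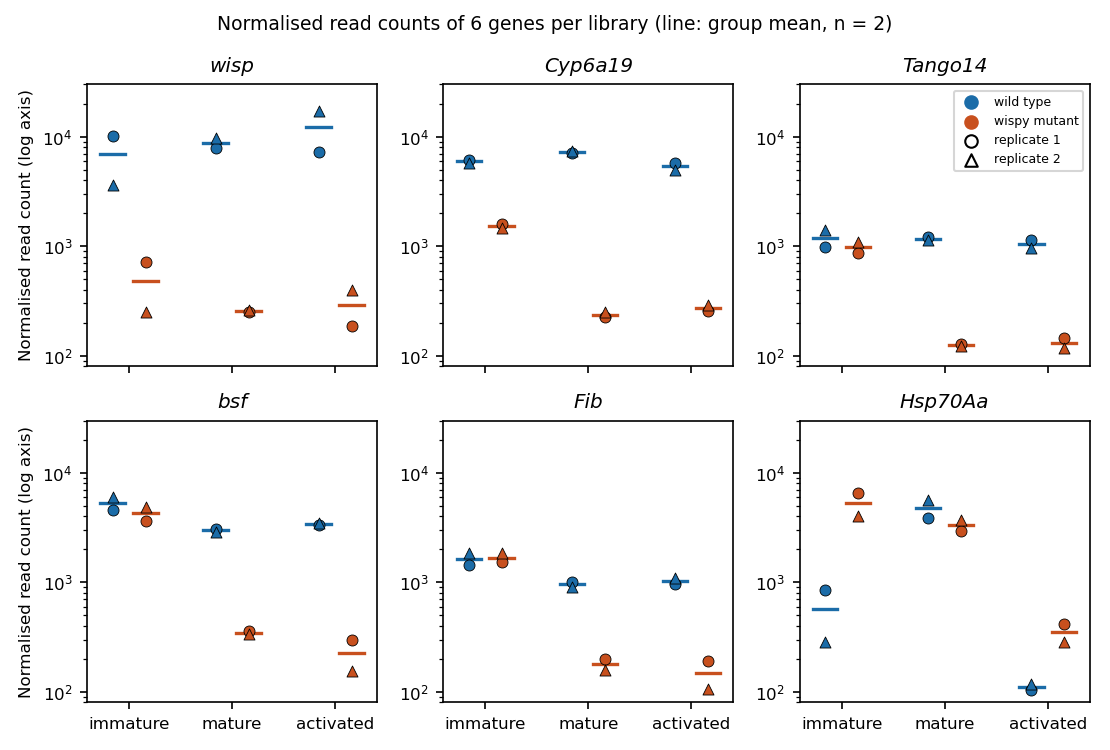
Normalised read counts on a log axis for wisp and 5 other genes, with 1 point per library, colour for genotype, shape for replicate and a line at the group mean (n = 2). Tango14, bsf and Fib lie near wild type in mutant immature oocytes and far below it in mutant mature oocytes and activated eggs.

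The comparison of mutant with wild type mature oocytes asks which transcripts differ between the 2 genotypes at the end of oogenesis. In mature oocytes 508 genes were lower and 37 higher in the mutant. The share of higher genes among the calls was 6.79% and depended on the fit. It was 6.4% with TMM scaling, 14% with quantile normalisation and 35.2% with only the mature libraries in the fit. With alternatives chosen after seeing the data it was 20% (block within each stage), 18.7% (length correction) and 44.1% (both). Among the named genes the largest decreases after wisp were in Cyp6a19, a cytochrome P450 (7227 ± 265 in wild type, 236 ± 17.7 in the mutant, SD, n = 2, log2 fold change -4.93, SE 0.163, limma adjusted p = 3.57e-06), Tango14 (log2 fold change -3.21) and bsf, an RNA-binding protein (log2 fold change -3.10). Pole2, a DNA polymerase epsilon subunit (-2.56), Fib, the nucleolar methyltransferase fibrillarin (-2.44), l(2)k09022 (-2.41) and Ubi-p5E, a polyubiquitin gene (-2.31), followed. Polyubiquitin genes share sequence with other copies, so the value of Ubi-p5E is uncertain. Among the higher genes were Sp7, a serine protease (log2 fold change 1.78), Pat1 (1.66), Argk, arginine kinase (1.38), Fdh, formaldehyde dehydrogenase (1.35), and GstS1, a glutathione transferase (1.27).

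By gene list, 20 of 65 mitochondrial ribosomal protein genes were lower in mutant mature oocytes and 0 higher (23 lower adjusted over the list alone). Examples are mRpS23 (log2 fold change -1.47), mRpL47 (-1.47) and mRpS11 (-1.43). The list median was -0.45 (camera adjusted p = 1.88e-07; adjusted p = 0.63 with an estimated correlation). Of 85 cytoplasmic ribosomal protein genes the median was 0.55 (camera adjusted p = 4.77e-21; adjusted p = 0.63 with an estimated correlation). Taken singly, 0 of these 85 were higher and 1 lower, also adjusted over the list alone. With a block for the replicate number within each stage, chosen after seeing the data, 34 were higher and 1 lower. That member, RpLP0-like (-0.90), is not a core ribosomal protein. Oxidative phosphorylation genes had a median of 0.30 (camera adjusted p = 1.02e-08; adjusted p = 0.63 with an estimated correlation), with 1 of 67 higher, CG9603 (0.69), and 1 lower, SdhC (-1.06), and 0 of either adjusted over the list alone. With that block 6 were higher and 1 lower. Proteasome genes (median 0.25, camera adjusted p = 4.74e-05), CCT chaperonin genes (0.23, camera adjusted p = 0.021), glycolysis genes (0.37, camera adjusted p = 0.021) and vacuolar ATPase genes (0.25, camera adjusted p = 0.00196) had 0 members called, and each had an adjusted p = 0.63 with an estimated correlation. Of 3 replication-dependent histone genes 1 was lower (2 adjusted over the list alone), His2B:CG33868 (-1.46), which shares reads with near-identical copies (median -0.66, camera adjusted p = 0.0286; adjusted p = 0.63 with an estimated correlation).

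Over all 5421 genes 508 were lower and 37 higher in mutant mature oocytes, and list counts near those shares do not single a list out. Of 42 genes for poly(A) tail control and translational repression, 5 were lower in mutant mature oocytes and 0 higher (5 lower adjusted over the list alone). They include wisp itself, Rga, a subunit of the deadenylase complex CCR4-NOT (2372 ± 119 in wild type, 799.3 ± 32.5 in the mutant, SD, n = 2, log2 fold change -1.57), CstF-50 (-1.28) and Not11 (-1.18). In the piRNA pathway 4 of 25 were lower (4 adjusted over the list alone): vls (-1.43), arx (-1.42), shu (-1.03) and csul (-0.71). The camera test of that list missed the threshold (adjusted p = 0.0526). So did the camera tests of the poly(A) tail, cell cycle, egg activation, axis patterning and Toll lists. In the cell cycle list 3 of 36 were lower, cort, a meiotic activator of the anaphase-promoting complex (-1.45), APC4 (-1.22) and ial, the Aurora B kinase (-0.93), and 1 was higher, APC7 (0.85), with the same counts adjusted over the list alone. Of 20 egg activation genes 2 were lower (2 adjusted over the list alone), wisp and cort. Of 28 maternal axis patterning genes 2 were lower (2 adjusted over the list alone), pll (-1.28) and ea (-1.13), and they are also the 2 calls among 11 genes of the dorsal group and Toll pathway. Of 41 translation factors 3 were lower, eIF2B-epsilon (-1.66), eIF-2beta (-1.40) and eIF2B-delta (-1.08), and Ef1alpha48D was higher (0.76), with the same counts adjusted over the list alone (camera adjusted p = 0.0286; adjusted p = 0.63 with an estimated correlation). In all 545 genes passed in limma at a Benjamini-Hochberg adjusted p of 0.05. Of the 41 named calls in mature oocytes 10 missed the threshold with TMM scaling, among them Pat1 (adjusted p = 0.0552), SdhC and csul, 4 with median-of-ratios scaling, and 29 with quantile normalisation, among them Argk, Fdh, mRpS23, mRpL47, mRpS11, cort, pll, vls, arx and shu. With quantile normalisation 50 genes passed, with TMM scaling 328, with only the 4 mature libraries in the fit 2274, and with a block for the replicate number within each stage 1302, the 545 among them. That block ended the camera call of translation factors (adjusted p = 0.05). Quantile normalisation also ended the camera calls of the mitochondrial ribosomal (median -0.096), proteasome (0.19), CCT (0.11), glycolysis (0.098), vacuolar ATPase (0.28) and translation factor lists (0.11), the last of which was lost too without mutant replicate 1 (0.28) or wild type replicate 2 (0.22). Leaving out a library gave 126 genes without mutant replicate 1, 195 without mutant replicate 2, 136 without wild type replicate 1 and 109 without wild type replicate 2.

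The same comparison in activated eggs gave 396 higher and 959 lower genes in the mutant. Among the lower genes besides wisp were Cyp6a19 (5364 ± 488 in wild type, 273.2 ± 21.5 in the mutant, SD, n = 2, log2 fold change -4.29), bsf (-3.97), l(2)k09022 (-3.60), Dcr-1, the microRNA-processing Dicer (-3.31), Tango14 (-3.00) and RpI1, the large subunit of RNA polymerase I (-3.00). Leaving out genes known only by annotation numbers, the higher genes were led by Hsp23, a small heat shock protein (1.94), GstE6 (1.81), Jheh2, a juvenile hormone epoxide hydrolase (1.72), GstD3 (1.71), Hsp70Aa (1.63), Sp7 (1.58) and GstS1 (1.57). Hsp70Aa belongs to a family of near-identical copies, so its value is uncertain. Of 85 cytoplasmic ribosomal protein genes 62 were higher and 0 lower (75 higher and 1 lower adjusted over the list alone), with RpL21 at 1.19 and RpS3A at 1.17. Their median was 0.94 (camera adjusted p = 3.49e-29; adjusted p = 0.855 with an estimated correlation). Among 67 oxidative phosphorylation genes 40 were higher and 1 lower (50 higher and 1 lower adjusted over the list alone), such as CG9603 (1.17) and CoVa (1.11), with a median of 0.76 (camera adjusted p = 1.21e-20; adjusted p = 0.855 with an estimated correlation).

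Further lists in activated eggs showed both directions. Over all 5421 genes 396 were higher and 959 lower, and list counts near those shares do not single a list out. Lists given here without a camera value missed the threshold of that test. Of 33 proteasome genes 4 were higher (3 adjusted over the list alone), with Prosbeta1 at 0.93 and Prosalpha5 at 0.78 (median 0.40, camera adjusted p = 5.72e-06; adjusted p = 0.855 with an estimated correlation). The 1 lower member, Prosap (-1.03), is a synaptic scaffold gene taken in by its symbol and not a proteasome subunit. In glycolysis 3 of 11 were higher, Tpi (1.03), Gapdh2 (0.96) and Gapdh1 (0.65), also 3 adjusted over the list alone, with camera adjusted p = 0.0235 (adjusted p = 0.855 with an estimated correlation). Of 17 vacuolar ATPase genes 2 were higher (0 adjusted over the list alone), VhaM9.7-c (0.67) and VhaAC39-1 (0.59), with camera adjusted p = 0.0235 (adjusted p = 0.855 with an estimated correlation). Mitochondrial ribosomal protein genes went both ways, 5 of 65 higher and 11 lower (5 and 11 adjusted over the list alone), with mRpS17 at 0.93 and mRpS30 at -1.41. Their median was -0.08 while the camera test pointed upwards (adjusted p = 0.908). In the list for poly(A) tail control 1 of 42 was higher and 11 were lower (1 and 11 adjusted over the list alone), led after wisp by Rga (-2.31), Not1, the scaffold of CCR4-NOT (-1.44), and pcm, the Xrn1 exonuclease (-1.40). In the piRNA list 5 of 25 were lower (5 adjusted over the list alone), with mino (-1.38), vls (-1.34) and spn-E (-0.97). The cell cycle list had 6 of 36 lower and 2 higher (5 and 2 adjusted over the list alone), among them mei-41, the ATR kinase (-2.15), and APC4 (-1.83). Of 20 egg activation genes 5 were lower (5 adjusted over the list alone), wisp, clos (-1.76), fs(1)N (-1.40) and Itp-r83A, the IP3 receptor (-1.35), among them. Of 28 maternal axis patterning genes 4 were lower and 2 higher (3 and 1 adjusted over the list alone), with ea (-1.61), pll (-1.47) and Myd88 (-1.39) lower and pgc (0.89) higher. Those 3 lower genes were also the called members of the Toll list. Of 7 heat shock genes 2 were higher (2 adjusted over the list alone), Hsp23 and Hsp70Aa, and the camera test missed the threshold (adjusted p = 0.0829). Of 41 translation factors 4 were higher and 4 lower (3 and 4 adjusted over the list alone), with eIF2B-epsilon at -2.20. Of 17 nurse cell and germline markers kel (-1.43) and cher (-1.11) were lower and osk higher (0.56), with 2 lower and 0 higher adjusted over the list alone. The sign of osk turned with quantile normalisation, where its log2 fold change was -0.04.

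Transcript length moved with these differences. In activated eggs the median log2 difference was 0.40 in replicate 1 and 0.59 in replicate 2 for the shortest transcripts (median 760 nt), and -0.53 and -1.05 for the longest (median 5735 nt). In mature oocytes the 8 bins of length lay between -0.14 and 0.023. After removal of the length trend from each library, an alternative chosen after seeing the data, 681 genes passed in activated eggs, against 1355 in limma on the values as deposited. With that correction 24 of the 63 named calls missed the threshold, among them Not1 (-0.45), pcm (-0.63), clos (-0.97), mino (-0.93), spn-E (-0.29), Itp-r83A (-0.28), cher (-0.18), Prosbeta1 (0.57) and slam (-1.05). Of the called genes 29.2% were higher with the values as deposited, 45% with TMM scaling, 48.9% with median-of-ratios scaling and 40.8% with quantile normalisation. The share was 12.4% with only the activated libraries in the fit, 29.8% with the length correction and 35.8% with a block within each stage. With that block and the length correction together 53.4% were higher, so the majority direction turned. TMM scaling moved the median of all genes in activated eggs from -0.16 to 0.028, and median-of-ratios scaling to 0.045. Quantile normalisation left 497 genes, and 24 of the 63 named calls missed the threshold with it, 8 with TMM and 6 with median-of-ratios scaling. Only the 4 activated libraries in the fit gave 476 genes. With a block for the replicate number within each stage 2909 genes passed, the 1355 among them, and the camera call of glycolysis genes was lost (adjusted p = 0.0804). Without 1 library the count was 967 (mutant replicate 1), 548 (mutant replicate 2), 903 (wild type replicate 1) and 203 (wild type replicate 2). The camera calls of glycolysis and vacuolar ATPase genes were lost without mutant replicate 1 (medians 0.32 and 0.22), the first also with quantile normalisation (0.28) and the second with the length correction (0.30). Of the ribosomal protein genes 11 were called without mutant replicate 1 and 0 without wild type replicate 2, where their median was 0.79.

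**Figure D3:**
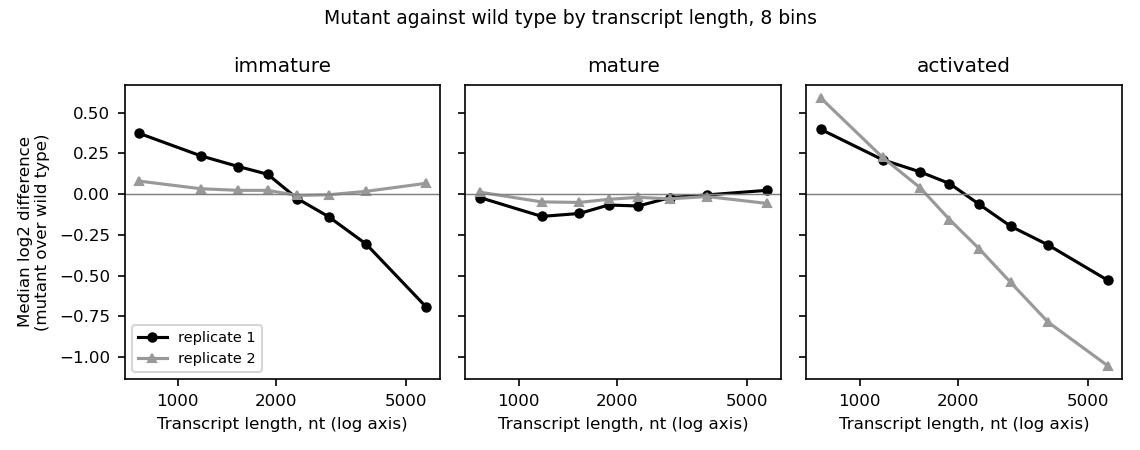
Median log2 difference of mutant over wild type against median transcript length in 8 bins of 674 or 675 genes, on a log axis, for each replicate and stage. In activated eggs both replicates run downwards from the shortest to the longest bin, in immature oocytes replicate 1 alone does, and in mature oocytes neither.

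Immature oocytes of the mutant differed from wild type in 6 genes, a count that rested on the treatment of the replicate number. With a block for the replicate number within each stage, chosen after seeing the data, 267 genes passed, 158 lower and 109 higher, the 6 among them. With 1 block over all stages 2 passed. The lower ones were Ubi-p5E (15680 ± 2050 in wild type, 3684 ± 6.93 in the mutant, SD, n = 2, log2 fold change -2.08, limma adjusted p = 0.00348), Cyp6a19 (-1.97, adjusted p = 0.00348), phr, a DNA photolyase (-1.97, adjusted p = 0.0348) and CG15047 (-1.25). CG13397 (1.93) and CG31683 (1.21) were higher. The 3 genes known by annotation numbers were chosen after their values were seen. Ribosomal protein genes had a median of 0.46 (camera adjusted p = 2.37e-22; adjusted p = 0.59 with an estimated correlation), oxidative phosphorylation genes 0.31 (camera adjusted p = 4.7e-12; adjusted p = 0.638 with an estimated correlation) and heat shock genes 0.60 (camera adjusted p = 0.00291; adjusted p = 0.59 with an estimated correlation). CCT chaperonin genes had a median of 0.26 (camera adjusted p = 0.034; adjusted p = 0.656 with an estimated correlation). Vacuolar ATPase genes had 0.26 (camera adjusted p = 0.00777; adjusted p = 0.59 with an estimated correlation) and translation factors 0.16 (camera adjusted p = 0.0251; adjusted p = 0.656 with an estimated correlation). Mitochondrial ribosomal protein genes had 0.14 (camera adjusted p = 0.00777; adjusted p = 0.717 with an estimated correlation), piRNA genes -0.13 (camera adjusted p = 0.00777; adjusted p = 0.656 with an estimated correlation) and replication-dependent histone genes -0.31 (camera adjusted p = 0.00777; adjusted p = 0.59 with an estimated correlation). In each of these lists 0 genes passed singly. With the block within each stage 4 of 25 piRNA genes, 2 of 41 translation factors and 1 of 3 replication-dependent histone genes were lower. That block also gave 2 of 7 heat shock genes, 1 of 65 mitochondrial ribosomal protein genes and 1 of 67 oxidative phosphorylation genes as higher. Across genes the differences in immature oocytes ran with transcript length (Spearman -0.521, with -0.68 in replicate 1 and -0.026 in replicate 2). The length correction turned the mitochondrial median to -0.067 and ended that call and the call of translation factors (0.091). With it the cytoplasmic ribosomal median was 0.24, that of oxidative phosphorylation 0.086, of vacuolar ATPase genes 0.11 and of replication-dependent histones -0.60, and these calls held at the preset correlation. The block within each stage ended the camera calls of CCT chaperonin genes (adjusted p = 0.0544) and translation factors (adjusted p = 0.0838). The cytoplasmic ribosomal protein call held without any 1 of the 4 libraries, and each of the other 8 was lost without at least 1. The median of heat shock genes was -0.038 without mutant replicate 1 and -0.19 without wild type replicate 2, and the call was lost in both. The piRNA call was lost without wild type replicate 1 (median 0.038) and mutant replicate 2 (-0.056), the histone call without mutant replicate 1 (-0.14) and wild type replicate 2 (-0.014), and that of oxidative phosphorylation without wild type replicate 1 (0.14). The mitochondrial call was lost without mutant replicate 1 (0.081) and without wild type replicate 1 (0.007, where the camera direction turned). Those of CCT, vacuolar ATPase and translation factor genes were lost without either mutant replicate or without wild type replicate 1, where the medians were 0.11, 0.20 and 0.17. At an unadjusted p of 0.05, 373 genes passed in limma. The count was 0 without mutant replicate 2, 0 without wild type replicate 2, 2 without mutant replicate 1, and 0 with only the 4 immature libraries.

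**Figure D4:**
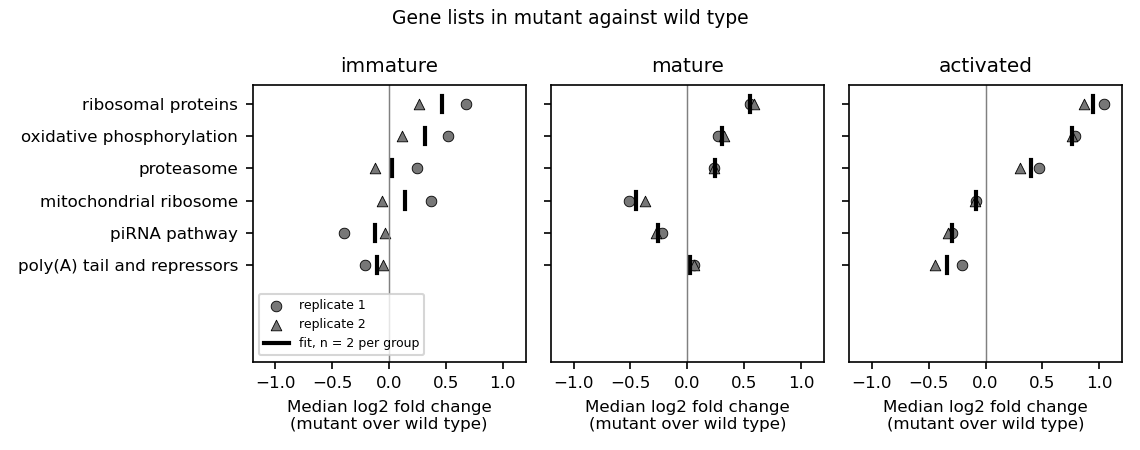
Median log2 fold change of mutant over wild type for 6 gene lists at each stage, with points for the difference within each replicate number and a bar for the fit (n = 2 per group). Ribosomal protein genes lie above 0 at each stage, at 0.46, 0.55 and 0.94.

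Wild type maturation compares mature with immature oocytes. With limma 0 genes passed, and 522 passed at an unadjusted p of 0.05. Immature replicate 1 lay closer to the mature libraries than to immature replicate 2, so the 0 calls do not show that few transcripts changed. CG3523, a fatty acid synthase listed as a fat body marker, was at 8896 ± 178 in immature and 594.7 ± 239 in mature oocytes (SD, n = 2, log2 fold change -3.96, limma adjusted p = 0.243). Values for His4:CG33907, a histone with many near-identical copies, were 6500 ± 1390 and 13320 ± 2210 (SD, n = 2, log2 fold change 1.04, limma adjusted p = 0.243). The ribosomal protein list had a median of -0.55 (camera adjusted p = 1.26e-36; adjusted p = 0.478 with an estimated correlation), with -0.33 in replicate 1 and -0.80 in replicate 2. Cell cycle genes had a median of 0.36 (camera adjusted p = 0.000426; adjusted p = 0.478 with an estimated correlation). In the heat shock list (median 0.79, camera adjusted p = 0.0417; adjusted p = 0.478 with an estimated correlation) and the piRNA list (0.45, camera adjusted p = 0.00648; adjusted p = 0.478 with an estimated correlation) 0 genes passed. Without wild type immature replicate 2 their medians were 0.11 and 0.013 and both calls were lost. Oxidative phosphorylation genes had a median of -0.28 (camera adjusted p = 5.56e-13; adjusted p = 0.478 with an estimated correlation) and translation factors -0.35 (camera adjusted p = 3.57e-07; adjusted p = 0.478 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of -0.15 (camera adjusted p = 3.57e-07) and CCT chaperonin genes -0.36 (camera adjusted p = 0.00134), each with an adjusted p = 0.478 with an estimated correlation. Without wild type immature replicate 2 these medians were -0.009 and -0.11 and both calls were lost. Replication-dependent histones were at 0.59 (camera adjusted p = 0.0417; adjusted p = 0.478 with an estimated correlation), a call lost without wild type immature replicate 1 (0.35) and with TMM scaling (0.49). Proteasome genes were at -0.05 (camera adjusted p = 0.0417; adjusted p = 0.698 with an estimated correlation), which turned to 0.13 without wild type immature replicate 2. Adjusted over the list alone, 2 replication-dependent histone genes, 1 variant histone gene and 1 heat shock gene were higher. Across genes, the maturation differences of the 2 replicates correlated at -0.039. Without wild type immature replicate 1 the count of genes was 1.

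Egg activation in wild type, mature oocytes against activated eggs, gave 3 lower genes and 0 higher. The planned replicate block over all stages kept 1 of these 3 calls. Hsp70Aa went from 4766 ± 1320 to 110.6 ± 8.66 (SD, n = 2, log2 fold change -5.39, limma adjusted p = 0.0148). LamC, a nuclear lamin, fell by 1.78 on the log2 scale (limma adjusted p = 0.0299). Sod3, a superoxide dismutase, went from 6994 ± 251 to 2242 ± 3.97 (SD, n = 2, log2 fold change -1.64, limma adjusted p = 0.017). Oocytes were dissected by hand and eggs were collected after laying, per the labels' protocols. Of 7 heat shock genes 1 was lower (2 adjusted over the list alone), Hsp70Aa (median -0.31, camera adjusted p = 0.0142; adjusted p = 0.853 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.26 (camera adjusted p = 6.67e-12; adjusted p = 0.853 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of -0.20 (camera adjusted p = 1.63e-09; adjusted p = 0.853 with an estimated correlation) and cytoplasmic ones -0.15 (camera adjusted p = 0.00231; adjusted p = 0.853 with an estimated correlation). The latter was 0.083 after the length correction and 0.011 without wild type activated replicate 2, and the call was lost without mature replicate 1 (-0.12). Replication-dependent histones were at -0.39 (camera adjusted p = 0.0142; adjusted p = 0.853 with an estimated correlation). Their call and that of the heat shock genes (0.081) were lost without wild type activated replicate 1. Without activated replicate 2 the calls of the histones (-0.42), of oxidative phosphorylation (-0.12) and of mitochondrial ribosomal protein genes (-0.077) were lost. The length correction ended the same 3 calls (medians -0.13, -0.043 and -0.004), and quantile normalisation ended the mitochondrial one (-0.068). Without any 1 of the 4 libraries, or with only these 4 in the fit, 0 genes passed.

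Mutant maturation changed 708 of 5421 genes, 617 lower and 91 higher in mature oocytes. Among the named genes the decreases were led by bsf (4271 ± 922 to 346.6 ± 16.1, SD, n = 2, log2 fold change -3.60, limma adjusted p = 0.000755), Fib (-3.24), Tango14 (-2.95), Adk2, an adenylate kinase (-2.76), and RpI1 (-2.69). Msh6, a mismatch repair protein (1.94), Men, malic enzyme (1.71), and glu, a condensin subunit (1.59), were among the higher. In the mitochondrial ribosomal list 38 of 65 were lower (45 adjusted over the list alone), with mRpL47 at -1.69 and mRpL23 at -1.60. Their median was -0.79 (camera adjusted p = 2.81e-16; adjusted p = 0.732 with an estimated correlation). Of 41 translation factors 7 were lower and 1 higher (8 and 1 adjusted over the list alone), with eIF2B-epsilon at -2.14. Among the cell cycle genes 3 of 36 were higher, such as BubR1 (1.15) and polo (0.93), and 2 lower, APC4 (-1.03) and cort (-0.95), with the same counts adjusted over the list alone (median 0.41, camera adjusted p = 0.00468; adjusted p = 0.732 with an estimated correlation). Of 6 variant histones His4r was lower (-1.14) and cid, the centromeric histone, higher (1.07), also adjusted over the list alone. Cytoplasmic ribosomal protein genes had a median of -0.46 with 3 of 85 lower, RpLP0-like (-1.47), RpS5a (-1.40) and RpL13A (-0.96), and 0 higher (2 lower adjusted over the list alone; camera adjusted p = 1.48e-07; adjusted p = 0.732 with an estimated correlation), and oxidative phosphorylation genes -0.27 with 2 of 67 lower, SdhC (-1.80) and CG3560 (-1) (2 adjusted over the list alone; camera adjusted p = 0.00208; adjusted p = 0.732 with an estimated correlation). With the length correction these medians were -0.16 and 0.03 and both calls were lost, the second also without immature replicate 1 (-0.25). Of the 42 named calls in mutant maturation 17 missed the threshold with quantile normalisation, 4 with TMM scaling and 4 with the length correction. The count was 127 without mature replicate 1, 157 without mature replicate 2, 450 without immature replicate 1, 335 without immature replicate 2, 273 with quantile normalisation and 209 with only these 4 libraries. Activation of mutant eggs gave 1 gene, cora, a cell junction protein (935.4 ± 70.7 to 175 ± 17.5, SD, n = 2, log2 fold change -2.41, limma adjusted p = 0.0324). The call of cora was lost without any 1 of these 4 libraries, and 1 other gene passed without activated replicate 1. The camera medians in mutant activation were 0.26 for cytoplasmic ribosomal proteins (adjusted p = 7.81e-12), 0.16 for mitochondrial ones (adjusted p = 2.34e-07), 0.21 for oxidative phosphorylation (adjusted p = 1.39e-07) and 0.45 for replication-dependent histones (adjusted p = 0.00629). Each had an adjusted p = 0.987 with an estimated correlation, and 0 members passed singly or adjusted over the list alone. Without activated replicate 1 the first 3 calls were lost (-0.007, 0.035 and 0.04), and with the length correction these medians were 0.004, -0.053 and -0.037. The cytoplasmic call was also lost with quantile normalisation (0.058), and the histone call with the length correction (0.10) and without mature replicate 2 (0.42).

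Whether maturation differed between genotypes was tested as an interaction, which uses the immature libraries whose replicates lay far apart. It passed for 56 genes, 0 of them with a more positive change in the mutant. With a block for the replicate number within each stage it passed for 531, the 56 among them, 508 with a more negative and 23 with a more positive change, but that block was chosen after seeing the data. The planned replicate block over all stages left 1 gene, quantile normalisation 1, the libraries compared alone 2 and the length correction 16. Cyp6a19 (log2 difference of changes -2.97, limma adjusted p = 0.00416), Tango14 (-2.96), bsf (-2.78) and Fib (-2.47) changed more negatively in the mutant, as did Hsp70Aa (-3.88, limma adjusted p = 0.0455). Scaling with TMM or by median of ratios left 2 genes each. Of the 10 named genes, Cyp6a19 alone kept its call with either scaling, with quantile normalisation and with the planned block, and 7 lost it with the length correction, among them bsf (-2.91) and Fib (-2.22). With TMM scaling the differences were -2.88 for Tango14, -2.70 for bsf, -2.40 for Fib and -3.80 for Hsp70Aa. That scaling shifts all genes of a library alike, so these small moves do not weigh against the lost calls. The count was 76 without wild type immature replicate 2, 9 without mutant immature replicate 2, 3 without wild type immature replicate 1, 1 without mutant immature replicate 1 or mutant mature replicate 2, and 0 without any of the other 3 libraries. Of 65 mitochondrial ribosomal protein genes 3 changed more negatively (21 adjusted over the list alone, 25 with the block within each stage), with a median of -0.62 (camera adjusted p = 4.37e-13; adjusted p = 0.897 with an estimated correlation). The interaction with activation passed for 0 genes in limma, with 444 at an unadjusted p of 0.05, and for 1 gene with the block within each stage.

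Across genes, the maturation fold changes of the genotypes correlated at 0.79 (Spearman 0.79), with 0.25 in replicate 1 and 0.91 in replicate 2. The activation fold changes correlated at -0.22 (Spearman -0.44), with 0.19 and 0.12 in the replicates, and at 0.33 after the length correction. Without wild type immature replicate 2 the correlation for maturation was 0.18, and without mutant activated replicate 1 that for activation was -0.025, without replicate 2 -0.37. Fold changes of mutant over wild type correlated at 0.73 between mature oocytes and activated eggs, 0.41 between immature and mature oocytes and 0.54 between immature oocytes and activated eggs. The last 2 were 0.074 and 0.16 without wild type immature replicate 2, and 0.10 and 0.036 without mutant immature replicate 1. In both mature oocytes and activated eggs 386 genes were lower, where independent lists of these sizes would share 89.9. These comparisons share no library, although the fit pools their spread.

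Few markers of other cell types are in the table, but this cannot tell whether other cells were present. A gene is listed only if it reached the floor of the table in each library, laid eggs included. A marker abundant in the dissected oocytes alone would therefore be missing too. Of 24 chorion and vitelline membrane symbols 0 matched, and likewise 0 of the antimicrobial peptide, haemocyte, midgut, neuronal and testis lists. The symbol closca among the 24 names the gene clos, which is in the table and was counted among the egg activation genes. The mitochondrially encoded list, which is not a cell type list, also has 0 members in the table. The follicle cell list has 5 members in the table, with 0 called in any comparison, the yolk list 1 (yl), the muscle list 1 (Tm1), the fat body list 1 (CG3523) and the early zygotic list 1, slam (-1.64 in mutant activated eggs against wild type, limma adjusted p = 0.0113). Of 9 genes for ecdysone synthesis and response 0 passed in any comparison.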

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

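The tests of the difference between genotypes were planned, and the block within each stage, the length correction and the test of the immature stage in the last paragraph were chosen only after the result was seen. Maturation differed between genotypes by the interaction test for 56 genes, for 1 with the planned replicate block over all stages, for 16 with the length correction and for 531 with a block within each stage. Among the named genes the difference of log2 changes (mutant minus wild type) was -3.88 for Hsp70Aa, -2.97 for Cyp6a19, -2.96 for Tango14, -2.78 for bsf, -2.47 for Fib, -1.51 for mRpL20, -1.50 for mRpL47, -0.98 for mRpL40, -1.30 for Rga and -1.40 for eIF-2beta. Only Cyp6a19 kept its call with the planned block and with TMM and median-of-ratios scaling. With TMM, which shifts all genes of a library alike, the differences were -2.88 for Tango14 and -2.70 for bsf. The length correction ended 7 of the 10 calls, among them bsf (adjusted p = 0.0916) and Fib (adjusted p = 0.0809). By camera in limma the medians of 3 lists differed for maturation, at 0.086 for cytoplasmic ribosomal proteins (adjusted p = 0.00541), -0.62 for mitochondrial ribosomal proteins (adjusted p = 4.37e-13) and 0.22 for proteasome genes (adjusted p = 6.33e-05), and each had an adjusted p = 0.897 with an estimated correlation. The cytoplasmic and proteasome calls were lost without wild type immature replicate 2 (-0.14 and 0.046) and with quantile normalisation (0.05 and 0.081), the first also without wild type mature replicate 2 (0.067) and with the block (adjusted p = 0.0507).

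For activation the camera medians differed for cytoplasmic ribosomal proteins (0.42), mitochondrial ribosomal proteins (0.39), oxidative phosphorylation genes (0.49), replication-dependent histones (0.84) and variant histones (0.49). Each had an adjusted p = 0.891 with an estimated correlation, and 0 genes passed singly in limma (444 at an unadjusted p of 0.05). After the length correction the first 3 medians were -0.058, -0.036 and 0.025, and both histone calls were lost (0.24 and 0.18). The variant histone call was also lost with TMM and median-of-ratios scaling (0.64 in both) and without mutant activated replicate 2 (0.24), mutant mature replicate 2 (0.60), wild type activated replicate 1 (0.42) or wild type mature replicate 1 (0.57).

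The genes lower in mutant mature oocytes were weighed against strain differences, since the mutant and w1118 may differ in more than wisp. Of 507 lower genes with coordinates 11 (2.17%) lay within 2000000 bases of wisp, against 166 of 4891 other genes (3.39%), an odds ratio of 0.631 (95% interval 0.307 to 1.17, two-sided Fisher exact p = 0.151), which argues against linkage to wisp for these genes as a set. In immature oocytes their median difference was 4.64% of that in mature oocytes in replicate 1 and 18.4% in replicate 2. In activated eggs their median log2 difference was -0.844 in replicate 1 and -1.087 in replicate 2, against -1.072 and -1.04 in mature oocytes. For these genes as a set the immature values argue against a strain difference of equal size at each stage. That rests on the immature stage alone, where the replicates lay far apart, and the genes were picked on the mature values. The median does not speak for single genes. The log2 fold change of Ubi-p5E was -2.083 in immature and -2.315 in mature oocytes, and that of Cyp6a19 -1.967 and -4.932. Strain differences in single genes, or that act only late in oogenesis, stay open. An effect of the genotype itself stays an untested hypothesis.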

How the results depend on the processing

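The length correction, the filter at a mean of 500, the block within each stage, the fit without immature libraries and the protein-coding fit are tests chosen only after the result was seen, and the others were planned. Pseudocounts of 0.5 and 5, no filter and a filter at 50 kept each count within 1.5 times its value, but the filters removed 0 genes and test nothing. ERCC scaling (0 ERCC rows) and a count model on recovered reads (reads not recovered) were not run. Unknown depth and the floor of 100 limit what low genes can show. Unless said otherwise, the cause of a change was not tested.

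Requiring an absolute log2 fold change of 1 left 399 genes in mutant maturation, 308 in mature oocytes (mutant against wild type, as below) and 649 in activated eggs, by construction. TMM gave 13 in immature oocytes, 328 in mature oocytes and 2 for the maturation interaction, and median of ratios gave 14 in immature oocytes and 2 for that interaction. Quantile normalisation gave 273 in mutant maturation, 2 in immature oocytes, 50 in mature oocytes, 497 in activated eggs, 1 for the interaction, -0.04 for osk, and -0.061 for the correlation of activation changes. Without an intensity trend the interaction had 35. The filter at 500, which tests fewer genes, gave 303 in mutant maturation, 213 in mature oocytes, 12 for the interaction and -0.16 for the activation correlation. Protein-coding records alone gave 15 in immature oocytes.

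The length correction gave 20 in immature oocytes, 681 in activated eggs, 16 for the interaction, 0.33 for the activation correlation (sign turned) and 0.89 for that of mutant effects in mature oocytes and activated eggs. It turned the camera direction, with medians of 0.083 (cytoplasmic ribosomal proteins) and -0.004 (mitochondrial) in wild type activation, 0.03 (oxidative phosphorylation) in mutant maturation, 0.004, -0.053 and -0.037 (cytoplasmic, mitochondrial, oxidative phosphorylation) in mutant activation, -0.067 (mitochondrial) in immature oocytes, and -0.058, -0.036 and 0.025 in the activation interaction. The medians at -0.004, 0.004 and 0.025 kept their sign. Camera with an estimated correlation lost each list call.

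With only the libraries compared, counts were 0 in wild type activation, 209 in mutant maturation, 2 in mutant activation, 0 in immature oocytes, 2274 in mature oocytes, 476 in activated eggs and 2 for the maturation interaction. Without the 4 immature libraries mutant activation had 2.

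With a replicate block wild type activation had 1, mutant activation 0, immature oocytes 2 and the interaction 1, and the other counts stayed within 1.5 times. Same-numbered libraries deviated together within each stage, but immature ones against the other stages. A replicate block within each stage, which has 3 residual and 16.1 prior degrees of freedom, gave 267 in immature oocytes, 1302 in mature oocytes, 2909 in activated eggs, 531 for the maturation interaction and 1 for that of activation, and with the length correction 263, 2123, 2687, 512 and 0. With both, 44.1% of the calls in mature oocytes and 53.4% in activated eggs were higher, against 6.79% and 29.2% in the main fit.

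With 1 replicate left out, the lone sample is assumed to vary like the other groups. Counts ranged from 0 to 1 in wild type maturation, 0 to 0 in wild type activation, 127 to 450 in mutant maturation, 0 to 1 in mutant activation, 0 to 5 in immature oocytes, 109 to 195 in mature oocytes, 203 to 967 in activated eggs, 0 to 76 for the maturation interaction and 0 to 0 for the activation interaction. Correlations ranged from 0.18 to 0.82 (maturation), -0.37 to -0.025 (activation), 0.074 to 0.50 (immature and mature), 0.62 to 0.77 (mature and activated) and 0.036 to 0.70 (immature and activated). Camera directions turned in 6 of 316 list tests with a library left out. Among them were proteasome genes in wild type maturation (median from -0.28 to 0.13, turned without wild type immature replicate 2), cytoplasmic ribosomal proteins in wild type activation (-0.30 to 0.011, without activated replicate 2) and in the maturation interaction (-0.14 to 0.29, without wild type immature replicate 2), mitochondrial ones in immature oocytes (0.007 to 0.31, without wild type replicate 1), and, among lists chosen later, nuclear pore genes there (-0.41 to 0.053, without wild type replicate 2). Medians alone also changed sign for heat shock genes in immature oocytes (-0.038 without mutant replicate 1, -0.19 without wild type replicate 2) and in wild type activation (0.081 without activated replicate 1), piRNA genes in immature oocytes (0.038 without wild type replicate 1) and cytoplasmic ribosomal proteins in mutant activation (-0.007 without activated replicate 1).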

Other observations

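The gene groups of the next paragraph and, in the last 2 paragraphs, the tests of length, mixing and scaling were chosen only after the result was seen, and the test with quantile normalisation was planned.

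Among glutathione transferases 8 of 14 were higher and 0 lower in mutant activated eggs against wild type, with a median of 0.74 (camera in limma, adjusted p = 9.71e-08; adjusted p = 0.238 with an estimated correlation). The family shares sequence, so single members are uncertain. Nucleolar ribosome assembly factors had 14 of 20 lower in mutant maturation, with a median of -0.98 (camera adjusted p = 3.34e-07; adjusted p = 0.0911 with an estimated correlation). Against wild type 7 were lower in mature oocytes (adjusted p = 0.301 with an estimated correlation) and 9 in activated eggs (adjusted p = 0.238 with an estimated correlation). Of 6 RNA polymerase subunits 4 were lower in mutant mature oocytes, with a median of -0.87 (camera adjusted p = 0.00878; adjusted p = 0.522 with an estimated correlation). Of 21 nuclear pore genes 9 were lower in mutant activated eggs (median -0.66, camera adjusted p = 0.0175; adjusted p = 0.536 with an estimated correlation), as were 8 of 31 aminoacyl-tRNA synthetases (adjusted p = 0.126) and 3 of 12 kinesin and dynein genes (camera adjusted p = 0.0274; adjusted p = 0.396 with an estimated correlation). Of 9 Tim and Tom genes 3 were higher there (camera adjusted p = 0.011; adjusted p = 0.238 with an estimated correlation). Differences in activated eggs ran with transcript length across genes (Spearman -0.578). After the length correction the medians there were -0.13 for nuclear pore, -0.05 for kinesin and dynein and 0.21 for Tim and Tom genes, with 2, 0 and 0 members called, and the 3 camera calls were lost (adjusted p = 0.0794, 0.796 and 0.272). Without wild type activated replicate 1 (-0.64) or mutant activated replicate 2 (-0.42) the nuclear pore call was lost, and the kinesin and dynein call without mutant activated replicate 1 (-0.53) or wild type activated replicate 2 (-0.34). The glutathione transferase median was 0.45 with 6 higher and that of the assembly factors -0.40 with 5 lower, and both calls held at the preset correlation (camera adjusted p = 0.00048 for each).

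In the replicates of immature oocytes, which lay apart along the first principal component in both genotypes, removing the length trend left 93.8% of the variance of the replicate difference in wild type and 93.5% in the mutant, and quantile normalisation left 100.2% in both, which argues against length bias as the whole cause and against differences of distribution left by the authors' normalisation. Mature oocyte RNA mixed in 1 share into immature replicate 1 would make its ratio to mature oocytes a rising straight line of the replicate 2 ratio, at any share and scaling. The line assumes no other deviation of these libraries, and a bootstrap over genes holds no spread between libraries. In wild type the median replicate 1 ratio was 1.005 (95% bootstrap interval over genes 0.996 to 1.014) for the 1099 genes with a replicate 2 ratio under 0.5, 0.889 (0.882 to 0.898) for the 2015 genes around a ratio of 1 (median 1.034) and 1.80 for the 71 over 2, so the middle lay -0.392 from the line, and in the mutant -0.239, which argues against such mixing as the whole cause. Mixing as a part of the cause stays open. The maturation differences of the replicates correlated across genes at 0.577 in the mutant, but replicates without mixing could give this too, so it cannot decide. The wild type value of -0.039 decides little, since the differences of replicate 1 had an SD of 0.339, against 0.921 in replicate 2 and 0.161 between the mature replicates. The labels put both replicates at stages 9 to 10, so no biological explanation was tested, and a difference between the sets in dissection or library making stays open.

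The higher ribosomal protein values in mutant activated eggs moved with transcript length. After the length correction their median was 0.60 in replicate 1 and 0.36 in replicate 2, against 1.04 and 0.87 before (camera adjusted p = 4.61e-14 after; adjusted p = 0.697 with an estimated correlation, with which the call was also lost before). By the medians and the preset correlation, the length trend removed here may account for part of the difference but not the whole. The call itself rests on that correlation. The correction used the median length of each gene's annotated transcripts, so length bias that this measure misses stays open. The list median was 1.13 with TMM and 1.15 with median-of-ratios scaling, while the median of all genes moved from -0.16 to 0.028 and 0.045. So the list stayed above 0 where the median of all genes lay near 0. Both methods shift all genes of a library alike, so the gap between this list and other genes could not change. They are therefore no test of the authors' normalisation as the cause, which stays open. An effect of genotype, and RNA recovery or degradation that differs between libraries by something other than length, stay open and were not tested.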
